A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

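There were 8 arrays, 1 per sample, each a 2-colour Agilent expression array of yeast genes. Per the labels' protocols, cDNA was primed with oligo dT and random nonamers mixed 1:1. The authors scanned all 8 arrays in 1 scan of 1 slide and extracted them with Agilent Feature Extraction 9.1.3.1, per the file headers, so slide and scan could not act as batches. The deposited scanner tables give, for each of 13048 spots per array, the mean signal and the median local background of both channels as intensity values on a linear scale. Per the file headers, they also hold processed intensity values, which Feature Extraction had corrected for background and for dye. The deposited log10 ratio of red (Cy5) over green (Cy3) was computed by the same program from those processed signals, per the file headers. Where both channels of a spot lay at the lower limit of the program, that ratio was set to 0, which held for 4.5% of the gene spots. The deposited series table of the authors holds log10 values. Setting each of its columns beside the scanner values of the same array showed them to be the same log10 ratios, turned to sample over reference and rounded (largest difference 0.005). The median of every column of that table was 0, and its scale, centring and direction are thereby known.

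The ratios were computed anew from the mean signals. Background was corrected with normexp (offset 50), and each array was normalized with loess in limma 3.58.1 under R 4.3.3 (with statmod 1.5.0 and version 1.17.8 of data.table), with control spots and spots marked as outliers at weight 0. In replicate 1 of every group the sample's own RNA carried Cy3 and the reference Cy5, and replicate 2 had the dyes the other way round, as the labels state. Each array was turned to sample over reference. Turned this way, the replicates of a group correlated at 0.903 to 0.954 across genes, and unturned at -0.886 to -0.94. The 2 spots of each of the 6256 gene probes were averaged, after 230 outlier spots among 100096 had been left out. Their log2 ratios differed with a median SD of 0.146. There was 1 probe per gene. Of the probes, 5756 matched a locus tag in the RefSeq gene table (assembly R64), which served for gene names and gene lengths alone, and 500 kept the name in the file. A probe was tested where it was well above background in the channel of the sample's RNA on at least 2 of the 8 arrays, which kept 5957 and left out 299. On each array 90.6% to 94.1% of probes met that condition, and 4 gene spots were saturated over all arrays. The number of arrays, 2 per group, limits the precision.

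The 4 group means were fitted to all 8 arrays with limma's lmFit and eBayes (4 residual degrees of freedom, 3.89 prior degrees of freedom), and p-values were adjusted with the Benjamini-Hochberg method over the 5957 genes, with an adjusted p under 0.05 as the threshold. Every adjusted p given for a gene comes from that fit unless another is named, and every error given as SE is that of the fitted log2 change. The 7 comparisons were refed against starved cells in polysomal and in non-polysomal RNA, the difference between these changes (an interaction contrast), polysomal against non-polysomal RNA in starved and in refed cells, and polysomal RNA of starved and of refed cells against the reference. The reference was a single RNA sample, so tests against it leave out its own spread. The labels call the samples biological replicates. Because a replicate number is also a dye orientation, samples with the same number were checked for shared deviations from their group means. All 6 pairs of groups showed them, with correlations of 0.505 to 0.707 across genes. The shared dye orientation alone could give these, so they do not show that the samples were paired in another way. The main fit leaves this shared part in its spread. The median SE of the change in polysomal RNA was 0.244 there and 0.179 with the number as a block. A fit with the number as a block (3 residual and 7.35 prior degrees of freedom) is given where it changes a call or moves a count by over 1.5 times.

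Gene lists were fixed from textbook knowledge before the data were examined: 23 lists with 1113 entries, of which 1023 were on the array. A list for noncoding RNAs had no probe, and 22 lists were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation) and with fry. All 79 list calls that camera made with the preset correlation were lost with the estimated one. That second test rests on the 4 residual degrees of freedom and had little power. Its failure therefore does not show that a list was unchanged. It failed even for trehalose and glycogen genes in starved polysomes against the reference (adjusted p = 0.11). There 20 of 21 were higher, with a median of 3.4 and an estimated correlation of 0.0388. Other lists had estimates far above the preset 0.01. These were 0.511 for ribosomal proteins, 0.673 for ribosome biogenesis factors, 0.688 for aminoacyl-tRNA synthetases and 0.489 for respiratory genes. For such lists the preset treats members that move together as nearly independent, so its p-values are likely much too small. Fry, which asks whether the members of a list changed and not whether they changed more than other genes, passed 51 of these 79 calls. In the order of the comparisons these were 2 of 9, 4 of 9, 0 of 7, 8 of 10, 10 of 17, 12 of 12 and 15 of 15. The genes named were also fixed by a rule beforehand. For refed against starved cells in each fraction and for the difference between fractions, these were the 10 with the largest rise and the 10 with the largest fall among genes past the threshold that have a standard name and the same sign in both replicates, and 5 each way for the other comparisons. Where no gene passed, the 5 with the largest statistic each way are given as values. Up to 4 members of each list described, by smallest p, and a fixed set of 10 genes complete the rule. The fixed set was GCN4, HAC1, HSP30, HSP26, HSP12, CDC19, PGK1, RPL3, PAB1 and PMA1. Not every gene of it is described in every comparison. Pairs of nearly identical genes, such as HXT6 and HXT7, RPL41A and RPL41B or EFT1 and EFT2, share sequence, and their probes may not tell them apart, so their values are uncertain.

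The fit was tested on simulated data with known answers, in which 200 of 5957 genes were changed. For polysomal RNA, refed against starved, it called 59 of 72 genes changed by 2 on the log2 scale, 15 of 58 changed by 1 and 0 of 70 changed by 0.5, with 4 false calls. For the difference between fractions it called 31 of 72, 0 of 58 and 0 of 70, with 5 false calls. The simulated noise was independent between genes and between arrays. Real samples with the same replicate number shared deviations, so these counts may not carry over to the data. Alternatives fixed beforehand were the replicate block, no background correction, the Feature Extraction ratios, median centring in place of loess, no filter or a stricter one on dim probes, the deposited series table, a fit of only the arrays compared and leaving out each array in turn. Scaling between arrays with Aquantile leaves ratios as they are. A choice of the brightest probe per gene and a slide block had nothing to act on. Checks of single patterns used 1000 lists of other genes matched on gene length or on brightness (25 neighbours each side) and Spearman correlations with gene length, known for 5606 genes (94.1%).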

Results

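Ribosome association of mRNAs was measured in the budding yeast Saccharomyces cerevisiae, strain background Sigma 1278b, around a brief loss of glucose. The cells grew at 30 °C in YPD, a rich medium with glucose, and received 3 µg/mL of thiolutin, an inhibitor of RNA polymerases. They were then moved to YPA, a medium without glucose, for 10 min (starved cells), and part of the culture was given 2% glucose for another 5 min (refed cells). RNA of polysomes, mRNAs that carry several ribosomes, and RNA from outside polysomes were each isolated. The 4 groups, starved polysomal, refed polysomal, starved non-polysomal and refed non-polysomal, had 2 biological replicates each. Every array also carried 1 common reference, polysomal RNA of cells grown with glucose, for which treatment with thiolutin is not stated. The median signal of the sample's own RNA was 2973 and 5773 on the starved polysomal arrays (replicates 1 and 2), 2053 and 3959 on the refed polysomal, 614.7 and 1206 on the starved non-polysomal and 645.1 and 1191 on the refed non-polysomal arrays. All changes are log2 values relative to the typical gene of each array, so they show unequal change among mRNAs, not change in total mRNA.

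Which mRNAs gained or lost weight in polysomes when glucose returned was asked first. The strongest rise in polysomal RNA, refed against starved, was that of PCL1 (YNL289W), a G1 cyclin of the Pho85 kinase, by 4.77 ± 0.34 (SE), or 27.3-fold (adjusted p = 0.000973). It lay at -4.71 ± 0.14 (SD, n = 2) against the reference in starved polysomes and at 0.06 ± 0.31 in refed ones. VHT1, the biotin transporter of the plasma membrane, rose by 3.24 ± 0.29, and TPO2, a polyamine exporter, by 2.70 ± 0.19. MET3 (ATP sulfurylase) and MET14 (adenylylsulfate kinase), both of sulfate assimilation, rose by 2.56 ± 0.36 and 2.04 ± 0.32. ARG5,6 of arginine synthesis (listed as ARG56) rose by 2.33 ± 0.20. YML018C, which has no standard name, rose by 2.78, and the other named genes with the largest rises were HLR1 (2.42), the putative permease gene SEO1 (2.26), EFM6, a methyltransferase of translation elongation factor 1A (2.06), and ZPS1, a zinc-regulated cell wall protein (2.06).

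Among genes with a standard name, hexose transporters fell most in polysomes, while YKR075C, which has none, fell by 4.04 ± 0.27. HXT6, a high-affinity transporter, fell by 3.06 ± 0.33 (8.34-fold lower, adjusted p = 0.00338), HXT3, a low-affinity one, by 2.98 ± 0.26 and HXT2 by 2.92 ± 0.31. MIG2, a repressor of glucose-repressed genes, fell by 2.86 ± 0.18. TMA10, a ribosome-associated stress protein, fell by 2.85, GAC1, which targets a phosphatase to glycogen synthase, by 2.81, and MPF1 by 2.83. The heat shock genes HSP30, a regulator of the plasma membrane proton pump, and APJ1, a J-domain chaperone, fell by 2.80 ± 0.25 and 2.74 ± 0.23. HSP26, a small heat shock protein, lay at 6.89 in starved and 6.88 in refed polysomes against the reference (adjusted p of the change = 0.997), but scale normalization gave a change of 1.63 (adjusted p = 0.0231). HAC1, the transcription factor of the unfolded protein response, had a change of -0.99 ± 0.26, which did not pass the test (adjusted p = 0.0627). It passed with the replicate block (adjusted p = 0.0036) and without replicate 1 of the starved group (-1.32, adjusted p = 0.0311), but not without replicate 2 (-0.65, adjusted p = 0.219). The change of PMA1, the plasma membrane proton pump, was -1.21 ± 0.68 (adjusted p = 0.327, or 0.0354 with the block). It hung on 1 array, at -2.36 without replicate 1 of the starved group (adjusted p = 0.0311) and -0.07 without replicate 2 (adjusted p = 0.952).

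The gene lists were examined next. Of 138 ribosomal protein genes, 29 passed the test in polysomal RNA, all of them higher. Adjusted over the list alone, 66 were higher and 1 lower, and with the replicate block 108 and 1. The median change of the list was 0.98, with 136 of 138 positive, and RPS14A (1.68 ± 0.19), RPL9B (1.59), RPL37B (1.46) and RPS16A (1.32) had the smallest p. Camera called the list (adjusted p = 6.56e-26), but not with an estimated correlation (adjusted p = 0.602) or with fry (adjusted p = 0.152). Of 26 genes of hexose transport and glucose sensing 10 fell (1 rose and 16 fell adjusted over the list alone, and also with the block), with a median of -0.80, among them HXT7 (-2.63 ± 0.23). Camera gave an adjusted p of 1.33e-10, and 0.0738 with an estimated correlation. Of 21 genes of trehalose and glycogen metabolism 6 fell (15 adjusted over the list alone, 17 with the block), and all 21 had negative values with a median of -0.93. TSL1 and TPS2, subunits of the trehalose synthase complex, fell by 1.77 and 1.35, and GSY1, a glycogen synthase, by 1.41. The camera test of that list had an adjusted p of 4.23e-10, and 0.0738 with an estimated correlation. Fry passed the hexose and the trehalose and glycogen lists (both adjusted p = 0.00152).

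Chaperones and heat shock proteins were mixed in polysomal RNA: of 41, 2 rose and 11 fell (3 and 14 adjusted over the list alone, 5 and 17 with the block), with a median of -0.35. HSP60 and HSP78, chaperones of mitochondria, fell by 1.77 and 1.54. The list passed camera (adjusted p = 0.00118), but not with an estimated correlation (adjusted p = 0.602). Of 25 ergosterol genes 6 fell (4 rose and 10 fell adjusted over the list alone, 4 and 13 with the block), including ERG3 (-1.98 ± 0.22) and ERG1 (-1.52 ± 0.21), both enzymes of sterol synthesis. Its adjusted p was 0.0202, and 0.647 with an estimated correlation. Of 35 genes of gluconeogenesis and alternative carbon use 3 fell (4 adjusted over the list alone; 2 rose and 12 fell with the block): the invertase gene SUC2 by 2.44 ± 0.19, the cytosolic malate dehydrogenase gene MDH2 by 2.58 ± 0.26 and the glycerol phosphate dehydrogenase gene GUT2 by 1.34 ± 0.27. Amino acid biosynthesis went both ways, with 9 of 78 genes higher and 12 lower (17 and 18 adjusted over the list alone, 23 and 19 with the block), and SER33 (1.64) and MET8 (1.31) among the higher ones.

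In all, limma called 325 of 5957 genes in polysomal RNA, refed against starved, 153 higher and 172 lower, each with the same sign in both replicates, and 1570 (758 and 812) with the replicate block. The count was 156 from the Feature Extraction ratios, 59 with median centring, 657 with scale normalization, 73 with the external control probes as the zero (2 higher and 71 lower, so that the higher calls were nearly all lost) and 70 from the 4 arrays compared alone. Without replicate 2 of the starved polysomal group it split into 70 higher and 74 lower, while it was 55 without replicate 1 and 56 without replicate 2 of the refed polysomal group. Among the named genes, SEO1 passed in none of these fits that left out 1 array (largest adjusted p = 0.167), EFM6 passed only without replicate 2 of the starved group, HLR1 failed without replicate 1 of the refed group, and MET3 and MET14 without replicate 2.

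**Figure D1:**
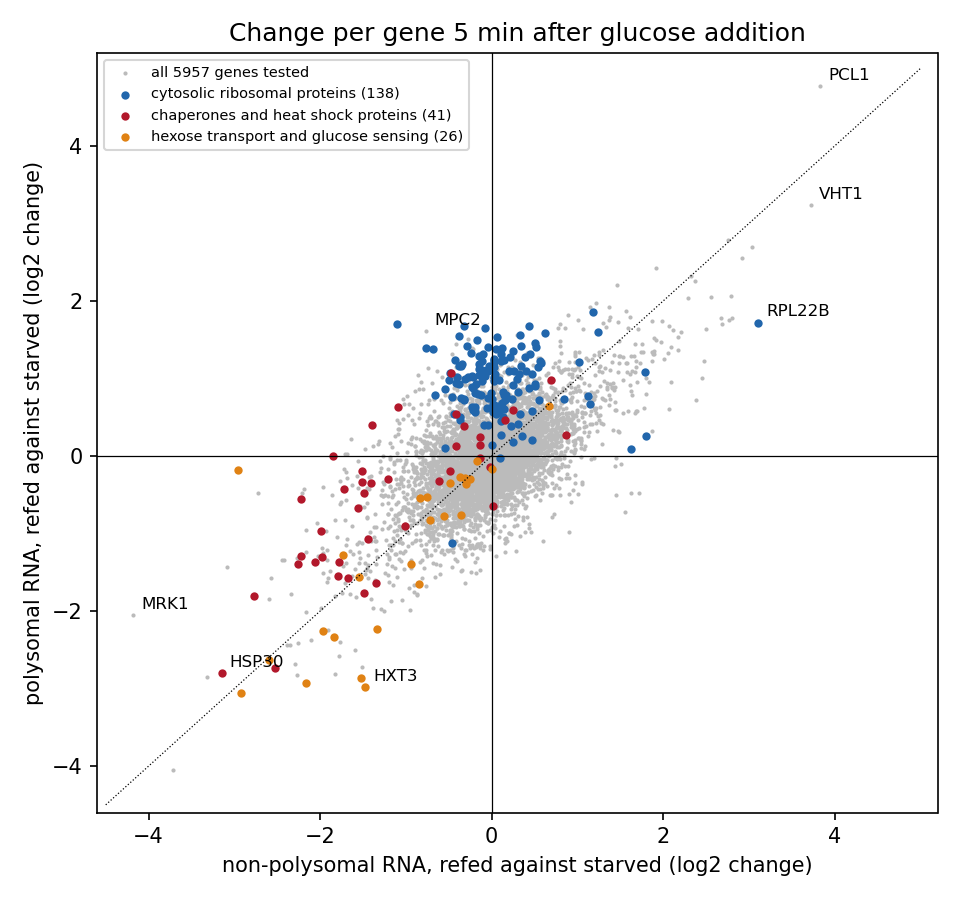
Change per gene (log2, refed against starved) in polysomal RNA (vertical axis) against non-polysomal RNA (horizontal axis). Grey points are the 5957 genes tested, coloured points are members of 3 gene lists, and the dotted line marks equal change. Of 138 ribosomal protein genes, 136 lie above 0 on the vertical axis and 77 to the right of 0 on the horizontal one.

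The same question was put to RNA outside polysomes. PCL1 rose here too, by 3.83 ± 0.34, and VHT1 by 3.72 ± 0.29, TPO2 by 3.04 ± 0.19 and MET3 by 2.93 ± 0.36. RPL22B, a paralog that codes for a large-subunit ribosomal protein, rose by 3.11 ± 0.25 (adjusted p = 0.00126), ALB1, a shuttling factor of large-subunit assembly, by 2.80 ± 0.20. STR3, an enzyme of sulfur amino acid synthesis, rose by 2.77, HPT1, the hypoxanthine-guanine phosphoribosyltransferase, by 2.69, EFM6 by 2.79 and RRT5 by 2.68. The largest fall was that of MRK1, a kinase of the GSK-3 family, by 4.19 ± 0.28 (18.2-fold lower, adjusted p = 0.00119). TMA10 fell by 3.32, HSP30 by 3.15, HXT6 by 2.93 and HXT7 by 2.60. BTN2, a sorting factor for misfolded proteins, fell by 2.77, RTC3 by 2.72, MTH1, a repressor of hexose transporter genes, by 2.96 ± 0.60, ATG39, a receptor for autophagy of the nuclear envelope, by 2.60 ± 0.48, and MAL33, an activator of maltose genes, by 2.58. HSP26 fell by 1.85 ± 0.36 (adjusted p = 0.0238). The change of HSP12, a membrane-associated stress protein, was -1.39 ± 0.64 (adjusted p = 0.243, or 0.00355 with the replicate block), and -0.45 and -2.34 without replicate 1 or 2 of the starved group.

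Chaperones stood out among the lists in non-polysomal RNA. Of 41, 23 fell and 1 rose (26 and 2 adjusted over the list alone), with a median of -1.41, and HSP42, a small heat shock protein, fell by 2.22 ± 0.22. Camera gave the list an adjusted p of 1.15e-13, and 0.124 with an estimated correlation, while fry passed it (adjusted p = 0.00358). Trehalose and glycogen genes fell in 11 of 21 cases (16 adjusted over the list alone, 17 with the block), with a median of -1.08, among them PGM2 (phosphoglucomutase, -1.94) and GLC3 (glycogen branching enzyme, -1.69). Hexose transport and sensing genes fell in 11 of 26 cases (1 rose and 16 fell adjusted over the list alone), with a median of -0.84. These lists had adjusted p of 2.51e-12 and 4.12e-10, and both 0.0832 with an estimated correlation, and passed fry (adjusted p = 0.00187 and 0.00251). Of 44 further stress genes of the Msn2 and Msn4 type, 8 fell and 1 rose (17 and 5 adjusted over the list alone, 22 and 6 with the block), for example USV1 (-2.17) and the glutamate decarboxylase gene GAD1 (-1.55), with an adjusted p of 0.374 for the list with an estimated correlation. Of 134 ribosome biogenesis factors 6 rose (4 adjusted over the list alone; 41 rose and 2 fell with the block), with a median of 0.34. They included RRS1 (1.43 ± 0.20) and BUD21 (1.34 ± 0.21), both of ribosome assembly, and the list's adjusted p was 6.29e-06, and 0.918 with an estimated correlation. Of 138 ribosomal protein genes 6 rose (4 adjusted over the list alone; 12 rose and 4 fell with the block), and the list did not pass camera (adjusted p = 0.371). Amino acid biosynthesis had 16 of 78 genes higher and 7 lower (22 and 12 adjusted over the list alone, 28 and 17 with the block), with SER33 (2.50) and SER2 (2.17) of serine synthesis among the higher.

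Over all genes, limma called 433 in non-polysomal RNA, 196 higher and 237 lower, and 1509 (707 and 802) with the replicate block. The count was 150 with median centring, 166 with scale normalization and 38 with external controls as the zero. It was 166 and 195 without replicate 1 or 2 of the starved non-polysomal group and 95 and 72 without replicate 1 or 2 of the refed one. MTH1 passed in none of the fits that left out 1 array (largest adjusted p = 0.153), ATG39 only without replicate 2 of the starved group and HSP26 only without replicate 1 of the refed group, while EFM6 and RTC3 failed without replicate 2 of the refed group.

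Changes in polysomal and non-polysomal RNA, which share no array, went together across genes (Pearson's r = 0.616, Spearman's rho = 0.522 over 5957 genes, which are not independent replicates). Of the called genes, 66 were higher in both fractions and 98 lower in both, where independent fractions would give 5.03 and 6.84. Both comparisons used the same estimate of each gene's spread, so a gene with a small spread was more easily called in both. The calls were therefore not independent, and these expected counts are only a rough guide. Those higher in both included PCL1, VHT1, MET3, SER33, ALB1 and RPL22B, and those lower in both HXT6, HXT3, HSP30, HSP82, TSL1 and SUC2. With the replicate block 292 were higher and 368 lower in both. Genes that were called higher in polysomal and lower in non-polysomal RNA numbered 0 in the limma fit, against 6.09 expected, and the opposite also 0, against 5.66. With the block these counts were 24 (102 expected), with the elongation factor genes TEF1 and TEF2, the ribosomal stalk genes RPP1A, RPP2A and RPP2B, and MPC2 and VMA16 among them, and 4 (96.4 expected), namely ACM1, CHS1, YSR3 and YER138W-A.

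**Figure D2:**
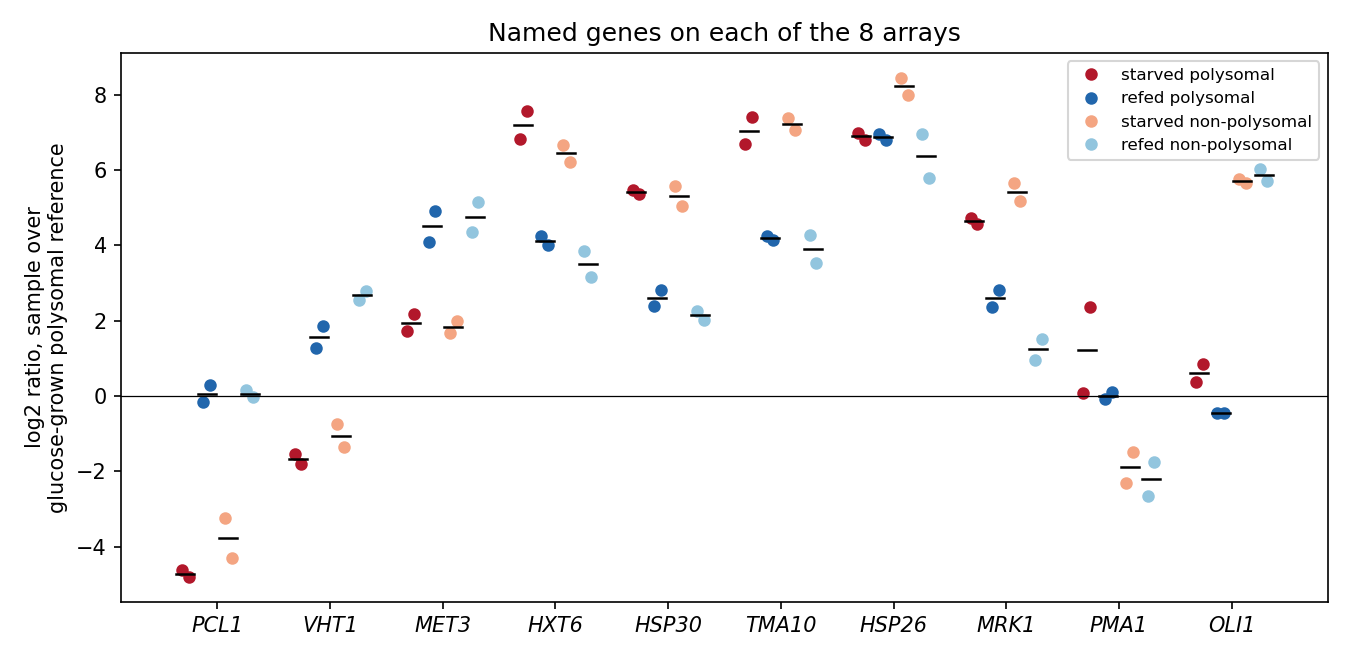
Log2 ratio of 10 named genes to the glucose-grown polysomal reference on each of the 8 arrays. Points are arrays, coloured by group, and bars are means of the 2 replicates. PCL1 lies near -4.71 in starved and 0.06 in refed polysomes, and OLI1 near 5.71 and 5.87 in the non-polysomal RNA of starved and refed cells.

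Whether glucose moved mRNAs between fractions, the question in the title of the series, was tested as the polysomal change minus the non-polysomal change. The largest statistics in favour of polysomes belonged to MPC2, a subunit of the mitochondrial pyruvate carrier, with a difference of 2.38 ± 0.32, RPS14A (2.00 ± 0.27), RIB4 of riboflavin synthesis (1.77 ± 0.26), VMA16, a membrane subunit of the vacuolar proton pump (1.63 ± 0.25), and the ribosomal stalk gene RPP2A (2.07 ± 0.32). The opposite way lay MIG2 (-1.34 ± 0.25), the mating kinase gene FUS3 (-1.50 ± 0.29), YSR3 of sphingolipid metabolism (-1.48), ACM1, an inhibitor of the anaphase-promoting complex (-1.88), and RPS9A (-1.54). None of the 5957 genes passed in limma (0 calls, smallest adjusted p = 0.237), and 517 had an unadjusted p under 0.05, 319 of them positive. With the replicate block 247 passed, 204 higher and 43 lower, among them all 10 genes just named (adjusted p = 0.0092 for MPC2 and 0.0229 for YSR3). HAC1, with a difference of -1.44 ± 0.36, HSP26, with 1.85 ± 0.51, and HSP12, with 1.79 ± 0.91, passed with the block (adjusted p = 0.0194, 0.0196 and 0.028), but the value of HSP12 was 0.85 and 2.74 without replicate 1 or 2 of the starved non-polysomal group.

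Among the lists, ribosomal protein genes had a median difference of 0.90 in favour of polysomes, with 126 of 138 positive. Adjusted over the list alone, 16 were higher and 2 lower, and with the block 43 and 3, for example RPP2B (2.81 ± 0.51) and RPL29 (1.54 ± 0.30). The camera test gave an adjusted p of 1.11e-22, and 0.598 with an estimated correlation. Chaperones had a median of 0.54 (3 higher adjusted over the list alone, 9 with the block), with HSP42 at 1.67 and HCH1, a cofactor of Hsp90, at 1.55, and plasma membrane and vacuolar proton pumps of 0.70 (5 higher both ways), with VMA7 at 1.77 and VMA8 at 1.18. Ribosome biogenesis factors had a median of -0.48, with 121 of 134 negative (5 lower with the block), and ALB1 at -1.02 and EFG1 at -1.22. Their adjusted p were 5.74e-08, 3.35e-05 and 1.4e-07, and 0.464, 0.374 and 0.704 with an estimated correlation. None of these lists passed fry (adjusted p = 0.487 for ribosomal proteins). The count of single genes with the block was 220 after median centring and 0 with the Feature Extraction ratios.

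The polysomes of starved cells were then compared with the RNA outside them. The highest polysomal over non-polysomal ratios among genes with a standard name were those of FLO11, the flocculin of the cell surface, at 3.34 ± 0.32 (adjusted p = 0.00105), PMA1 at 3.12 ± 0.68, the fatty acid synthesis genes ACC1 at 2.82 ± 0.30 and FAS2 at 2.82 ± 0.33, and LEU1 of leucine synthesis at 2.76 ± 0.32. The lowest was that of OLI1, a mitochondrial gene for a subunit of ATP synthase, at -5.09 ± 0.23 (34.1-fold lower, adjusted p = 0.000113). The ribosomal protein genes RPL29 (-3.23 ± 0.21), RPL41B (-3.12 ± 0.23) and RPL41A (-3.07 ± 0.22) and the mitochondrial COX3 (-3.00 ± 0.36), which codes for a subunit of cytochrome oxidase, were the next lowest with a standard name. GCN4, the transcription factor of amino acid starvation, was higher in polysomes by 1.22 ± 0.37 (adjusted p = 0.0334), and HSP26 and HSP12 were lower there by values of -1.34 ± 0.36 (0.13 with scale normalization and 0.88 with external controls) and -2.23 ± 0.64. Other genes of the fixed set hung on single arrays. Without replicate 1 or 2 of the starved polysomal group, CDC19 lay at 2.74 and 0.02, RPL3 at 0.81 and -1.48 and PAB1 at 1.54 and 0.03. PGK1 lay at 0.63 without replicate 2 of that group.

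Of 138 ribosomal protein genes 97 were lower in starved polysomes than outside (103 adjusted over the list alone, 122 with the block), with a median of -1.66. Camera gave an adjusted p of 4.15e-22, and 0.572 with an estimated correlation, and fry 0.0204. Mitochondrial ribosomal protein genes were lower in 39 of 72 cases (1 higher and 41 lower adjusted over the list alone), with a median of -0.82, for example MRPL39 (-2.57), and transcripts of the mitochondrial genome, which cytosolic ribosomes do not translate, in 5 of 11 (7 adjusted over the list alone, 10 with the block), with a median of -1.34. Cell wall genes were higher in polysomes in 31 of 54 cases and lower in 1 (33 and 1 adjusted over the list alone), including GSC2, a glucan synthase (2.24), and CCW14 (2.11), with an adjusted p of 0.482 for the list with an estimated correlation. Aminoacyl-tRNA synthetases were higher in 10 of 22 cases (13 adjusted over the list alone, 19 with the block), led by THS1 (2.26) and KRS1 (2.03), and trehalose and glycogen genes in 11 of 21 (13 adjusted over the list alone), led by GAC1 (2.27) and TPS2 (2.17). Adjusted p with an estimated correlation were 0.572 and 0.655 for the mitochondrial lists, 0.655 for the synthetases and 0.482 for trehalose and glycogen. Over all genes this ratio rose with gene length, in starved and in refed cells, as given further below. The lists were not matched on length for it, so their values between fractions may partly follow length.

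In starved cells limma called 2429 genes between the fractions, 1233 higher and 1196 lower in polysomes. Median centring gave 1376 and 757, the 4 arrays alone 1548 in all, and external controls as the zero, which raise the typical polysomal gene by 2.25, 4985 and 2. PMA1 failed without replicate 1 of the starved non-polysomal group (2.71, adjusted p = 0.0539), GCN4 failed without replicate 2 of the polysomal (0.64) or either array of the non-polysomal group, and HSP26 and HSP12 failed without replicate 2 of the polysomal (-1.25 and -1.90) or replicate 1 of the non-polysomal group (-1.12 and -1.28).

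In refed cells the highest polysomal over non-polysomal ratios among genes with a standard name were those of 5 genes. YDJ1, an Hsp40 co-chaperone, lay at 2.61 ± 0.28 (adjusted p = 0.00325), SSA2, an Hsp70, at 2.56 ± 0.45, EFT1 and EFT2, which both code for elongation factor 2, at 2.48 ± 0.61 and 2.45 ± 0.54, and ACC1 at 2.35 ± 0.30. The lowest was again OLI1 at -6.32 ± 0.23 (79.8-fold lower, adjusted p = 2.1e-05), and low ratios were also those of RPL7B (-3.19 ± 0.37), COX3 (-2.97 ± 0.36), RPS14B (-2.86 ± 0.29) and RPS30B (-2.83 ± 0.33). HAC1 was lower in polysomes at -1.39 ± 0.26 (adjusted p = 0.00764), and PMA1 higher at 2.21 ± 0.68 (adjusted p = 0.0395).

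Chaperones were higher in refed polysomes than outside in 22 of 41 cases and lower in 1 (23 and 1 adjusted over the list alone), with a median of 0.99, including HSP104, a disaggregase (2.11), and SBA1, a cofactor of Hsp90 (1.61). Trehalose and glycogen genes were higher in 13 of 21 cases, and also 13 adjusted over the list alone, with NTH1, a trehalase, at 1.58. Synthetases of aminoacyl-tRNA were higher in 10 of 22 (15 adjusted over the list alone, 19 with the block) and cell wall genes in 18 of 54, with 1 lower, counts that stayed at 18 and 1 adjusted over the list alone (27 and 5 with the block). Ribosomal protein genes were lower in 41 of 138 cases (40 adjusted over the list alone; 1 higher and 85 lower with the block), with a median of -0.60. Mitochondrial ribosomal proteins were lower in 38 of 72 and higher in 1 (43 and 2 adjusted over the list alone), and mitochondrial genome transcripts lower in 6 of 11 (9 adjusted over the list alone, 11 with the block). Camera called all of these lists (adjusted p = 4.95e-06 for chaperones, 1.74e-09 for mitochondrial ribosomal proteins and at most 0.000939), but with an estimated correlation the adjusted p was 0.485 for ribosomal proteins (0.11 with fry), 0.452 for synthetases and 0.317 for the other lists.

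Over all genes limma called 1900 in refed cells, 959 higher and 941 lower in polysomes, and 3230 (1598 and 1632) with the replicate block. Median centring split its calls 968 to 442 and external controls, which raise the typical gene by 1.6, 3662 to 2, and the count was 723 and 501 without replicate 1 or 2 of the polysomal group and 688 and 649 without replicate 1 or 2 of the non-polysomal one. EFT1 and PMA1 passed in none of these 4 fits (adjusted p up to 0.115 and 0.196), EFT2 failed without replicate 2 of the polysomal or replicate 1 of the non-polysomal group (2.14 and 2.11), and HAC1 failed without replicate 1 of the polysomal or replicate 2 of the non-polysomal group (-1.31 and -1.25) and turned to 0.23 with external controls.

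**Figure D3:**
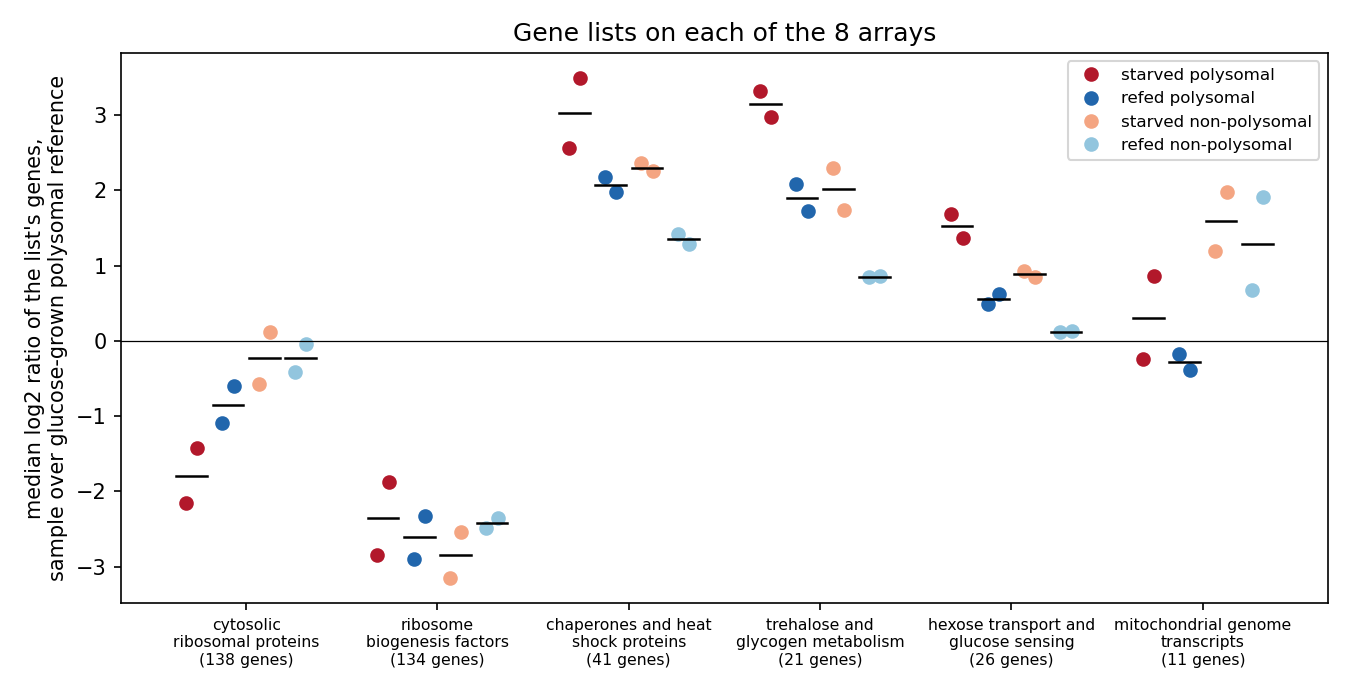
Median log2 ratio to the glucose-grown polysomal reference of 6 gene lists on each of the 8 arrays. Points are arrays, coloured by group, and bars are means of the 2 replicates. Ribosomal proteins lie at -2.15 and -1.42 on the starved polysomal arrays and at -1.09 and -0.60 on the refed polysomal ones, and chaperones at 2.56 and 3.49 and at 2.17 and 1.98.

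Starved polysomes were then set against polysomes of glucose-grown cells. Thiolutin treatment of that reference is not stated, so effects of starvation and of the inhibitor cannot be told apart here. The same holds for refed polysomes against the reference. BTN2 lay at 7.69 ± 0.18 (207-fold higher, adjusted p = 2.74e-07), HXT6 at 7.18, TMA10 at 7.04, HSP26 at 6.89 and HSP82, an Hsp90, at 6.78. ALB1 lay at -5.15 ± 0.14 (35.5-fold lower), the nucleolar protein gene NSR1 at -4.78, PCL1 at -4.71, the arginine methyltransferase gene HMT1 at -4.48 and AIR1 of nuclear RNA surveillance at -4.38. Of 134 ribosome biogenesis factors 133 were lower, the same count adjusted over the list alone, with a median of -2.34, and of 138 ribosomal protein genes 129 were lower (130 adjusted over the list alone), with a median of -1.77. Of 41 chaperone genes 32 were higher and 5 lower, both also adjusted over the list alone, with a median of 3.05 and HSP78 at 6.36. Trehalose and glycogen genes were higher in 20 of 21 cases, hexose transport and sensing genes in 23 of 26 with 1 lower, and other stress genes in 38 of 44 with 2 lower, all the same adjusted over the list alone. Adjusted p with an estimated correlation were 0.373 for biogenesis factors and for ribosomal proteins, 0.225 for chaperones, 0.11 for trehalose and glycogen, 0.136 for hexose transport and 0.183 for other stress genes. Limma called 3624 genes, 1889 higher and 1735 lower. With the external controls as the zero it called 2595, and the split moved to 2153 higher and 442 lower.

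Refed polysomes still differed from the reference in 3155 genes, 1616 higher and 1539 lower. ADH7, an alcohol dehydrogenase, was highest at 6.92 ± 0.40 (121-fold higher), followed by HSP26 at 6.88, HSP42 at 5.99, RGI1, a protein of respiratory growth, at 5.90 and BTN2 at 5.89. The lowest were AAH1, the adenine deaminase, at -4.28 ± 0.38, CHA1, the serine and threonine deaminase, at -3.99, ALD5, a mitochondrial aldehyde dehydrogenase, at -3.88, URA7, a CTP synthetase, at -3.82 and DHR2, an RNA helicase of ribosome assembly, at -3.75. All 134 ribosome biogenesis factors were lower (134 adjusted over the list alone), with a median of -2.62, while ribosomal protein genes were lower in 88 of 138 cases and higher in 1 (91 and 1 adjusted over the list alone), with a median of -0.85. Chaperones were higher in 31 of 41 cases and lower in 3 (33 and 3 adjusted over the list alone), with a median of 2.08. Genes of hexose transport and sensing were higher in 14 of 26 cases and lower in 3, the same adjusted over the list alone, with HXT7 at 4.03. With an estimated correlation these lists had adjusted p of 0.343, 0.53, 0.205 and 0.257. The count was 1777 without replicate 1 of the refed polysomal group and 1269 with the external controls as the zero.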

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

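Some of what follows was chosen after the data were seen, and this is said where it applies. Ribosomal protein mRNAs were a surprise, because their changes on the return of glucose differed between fractions: in polysomal RNA 136 of 138 were positive (29 passed, median 0.98), and outside polysomes 77 (6 passed, median 0.03). In the interaction contrast, tested with camera at the preset correlation, their median difference was 0.897 (adjusted p = 1.11e-22), and it was lost with an estimated correlation (adjusted p = 0.598). Other lists differed between fractions in the same test: proton pumps by 0.697 (VMA16 and VMA7 foremost), chaperones by 0.542, genes of the respiratory chain and TCA cycle by 0.392 (LSC1, a succinyl-CoA ligase, at 1.29), other Msn2 and Msn4-type stress genes by 0.389 (GRE3, an aldose reductase, at 1.45), cell wall genes by -0.349 (FLO11 at -1.49) and ribosome biogenesis factors by -0.485. Their camera adjusted p were 3.35e-05, 5.74e-08, 0.000277, 0.000294, 0.000448 and 1.4e-07 in that order, and 0.374, 0.464, 0.704, 0.515, 0.515 and 0.704 with an estimated correlation. Of these lists, with no single gene past the threshold in any, the replicate block called 5 pumps, 9 chaperones, 7 respiratory and 10 stress genes higher and 1 cell wall gene and 5 biogenesis factors lower.

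For the rise of ribosomal protein mRNAs in polysomes, 3 explanations were written before the test and another afterwards. Short genes might have risen as a whole, but the upper bound of the central 95% of 1000 lists matched on gene length was 0.202, against 0.978 observed, and for the difference between fractions it was 0.22, against 0.897, so length does not account for it. A single replicate or dye orientation could have carried the rise, but the list rose by 1.07 in replicate 1 and by 0.918 in replicate 2, above the matched upper bounds of 0.451 and 0.0323, which argues against that. Bright probes might have risen as a whole, but lists matched on brightness had an upper bound of 0.237, and 0.293 for the difference between fractions, so it does not account for the rise either. The genes of matched lists were drawn one by one, while ribosomal protein genes moved together (estimated correlation 0.511). The bounds are therefore too narrow for noise that the whole list shares. They do not show that the rise exceeds such noise.

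The explanation added afterwards is that all other mRNAs may have left the polysomes while ribosomal protein mRNAs stayed. Taken against the external control RNA, the ribosomal protein median moved by 0.769 in replicate 1 and by -0.188 in replicate 2 (mean 0.29), so the replicates differ in sign. These data cannot tell whether ribosomal protein mRNAs gained ribosomes or lost fewer than the rest. Absolute amounts per cell, from control RNA added in a known amount per cell before fractionation, would decide it.

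The external control probes, looked at after the main results, showed the other surprise. Relative to 10 control probes with 200 spots on each array, the median gene was higher in polysomal than in non-polysomal RNA by 2.48 and 2.02 in starved cells (mean 2.25, 4.76-fold) and by 1.81 and 1.4 in refed cells (mean 1.6, 3.04-fold). From starved to refed cells it changed by -0.331 and -1.13 in polysomal RNA and by 0.337 and -0.508 in non-polysomal RNA. The labels do not say how much control RNA was added or at what step, so these values were not used to rescale the main results.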

How the results depend on the processing

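Fixed beforehand were the replicate block, the background, filter, ratio and centring alternatives and each array left out. Scale normalization, external controls as the zero, and the block combined with other ratios were chosen after the results were seen. Without background correction the counts were 348, 432, 0, 2422, 1889, 3627 and 3159 in the order of the comparisons, and without a filter 326, 434, 0, 2423, 1902, 3643 and 3173. Of 2348 checks on the values of 155 named genes 2065 stayed the same, 113 were weaker, 77 stronger, 88 moved and 5 reversed (a changed sign where the gene passed in either fit). In all 69 changed sign, 64 of them with no pass in either fit. The 2348 include 155 checks with Aquantile, which leaves ratios as they are and could not differ. They also include 155 with the deposited series table, which repeats the Feature Extraction ratios, and the filter alternatives, which alter no gene's ratio. The number that stayed the same thus overstates how stable the values were. Of 237 checks on list calls 145 stayed the same and 92 were weaker, 79 of these with the estimated correlation.

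In polysomal RNA, refed against starved, the 325 calls became 1570 with the block, 156 with Feature Extraction ratios, 155 with the deposited series table, 59 (21 higher, 38 lower) with median centring, 657 with scale normalization, 73 (2 and 71) with external controls and 70 from the compared arrays alone. Leaving out 1 array gave 55 to 309. In non-polysomal RNA the 433 calls became 1509 with the block, 150 (61 and 89) with median centring, 166 with scale normalization, 38 (14 and 24) with external controls and 72 to 195 without 1 array. The 0 calls for the difference between fractions became 247 with the block, 220 (200 and 20) with the block after median centring and 0 with the block on Feature Extraction ratios.

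Between fractions, starved cells went from 2429 calls to 4987 with external controls and to 1548 from the compared arrays alone, and to 1651 to 2381 without 1 array. Refed cells went from 1900 to 3230 with the block, 3664 with external controls and 501 to 723 without 1 array. Median centring raised the median of all genes from 0.0261 to 0.171 and from -0.0147 to 0.107, and the share of higher calls from 50.8% to 64.5% and from 50.5% to 68.7%, and lowered it from 47.1% to 35.6% in polysomal RNA. Against the reference the counts were 2899 to 3195 (starved) and 1777 to 2104 (refed) without 1 array. With external controls starved cells had 2595 calls, and their split moved from 1889 higher and 1735 lower to 2153 and 442. For refed cells the count with external controls was 1269 (617 and 652). The counts moved in both fractions became 24, 4, 292 and 368 with the block.

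The reversed values were those of HSP26 in polysomal RNA (1.63 with scale normalization), HSP26 between fractions in starved cells (0.128 with scale normalization, 0.875 with external controls), RPL3 there (1.87) and HAC1 in refed cells (0.226), both with external controls. Median centring lost 12 list calls: ergosterol genes in polysomal RNA (adjusted p = 0.0577), histone genes in non-polysomal RNA (0.105), between fractions in starved cells amino acid (0.108), glycolysis (0.677) and hexose transport genes (0.15), and in refed cells amino acid, ergosterol and translation factor genes (each 0.0807), glycolysis (0.196), hexose transport and other stress genes (each 0.203) and histones (0.074). The block made 1 list call weaker (ergosterol genes in refed polysomes against the reference, adjusted p = 0.0641) and no other call of a named gene or list weaker. The cause was not tested.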

Other observations

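Some list results not described so far, between fractions, against the reference or on refeeding, are given here. Genes of mRNA decay and P bodies were higher in starved polysomes than outside in 17 of 39 cases and lower in 6 (20 and 6 adjusted over the list alone), with XRN1, the 5' exonuclease, at 2.19 ± 0.18 and the Ccr4-Not gene NOT3 at 1.51, and in refed cells in 14, with 5 lower (16 and 5 adjusted over the list alone; 22 and 7 with the block). Camera's adjusted p were 0.0217 and 0.011, and 0.572 and 0.317 with an estimated correlation. Proteasome genes were higher in refed polysomes than outside in 9 of 33 cases (8 adjusted over the list alone). In refed polysomes against the reference they were higher in 23 of 33 cases (26 adjusted over the list alone), and genes of the respiratory chain, ATP synthase and TCA cycle in 49 of 54, also 49 adjusted over the list alone, with the citrate synthase gene CIT1 at 3.28 and SDH2 at 2.85. These lists had camera adjusted p of 2.85e-06 and 2.68e-13, and 0.228 and 0.389 with an estimated correlation. Histone genes rose in non-polysomal RNA in 2 of 11 cases (5 adjusted over the list alone, 7 with the block), with a median of 0.72, and their adjusted p was 0.00476, and 0.374 with an estimated correlation.

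The genes that rose in both fractions within 5 min, although an inhibitor of transcription was present, form the next pattern. The 66 genes, PCL1, VHT1, MET3 and SER33 among them, had median rises of 1.43 in polysomal and 1.70 in non-polysomal RNA. Of them, 39 (59.1%) were lower in starved polysomes than in the reference, as were 1735 of all 5957 genes. The same starved polysomal arrays served to choose the 66 genes, which by itself favours low values there. Their share is therefore not separate evidence. Signal near background could have raised their ratios, but 66 of 66 (100%) were well above background on all 8 arrays, which argues against it. This count covers the channel of the sample's RNA, with at least 1 spot per probe, and leaves out the reference channel. On each array 90.6% to 94.1% of all probes met the same condition. Loss of all other mRNAs, an explanation added after the data were seen, might raise stable mRNAs in both fractions. Against the external controls the median gene changed by -0.331 and -1.13 in polysomal and by 0.337 and -0.508 in non-polysomal RNA. No fall was as large as the median rise, but that of -1.13 was larger than the smallest polysomal rise among these genes (0.85). With the external controls as the zero, only 2 genes were called higher in polysomal RNA. That zero differs between replicates, however, which widens the spread of every gene. In non-polysomal RNA the calls fell as well, from 433 to 38, although the median gene moved there by a mean of only -0.0855. The loss of calls may thus be a loss of power and does not bear on this explanation. The replicates differ and how the controls were added is not stated, so this explanation stays undecided. New transcription despite thiolutin may also have raised them, likewise added afterwards, and with 0 samples without the inhibitor these data cannot tell. Cells refed with a different inhibitor, or an RNA polymerase II mutant, would settle it.

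Gene length went with the fraction in every sample. Spearman's rho between length and the polysomal over non-polysomal ratio was 0.642 and 0.657 in starved cells and 0.543 and 0.533 in refed cells (replicates 1 and 2), and without ribosomal protein genes 0.632, 0.648, 0.532 and 0.527. In starved cells the median ratio was -0.90 for the 641 genes under 500 bp and 1.18 for those over 3000 bp, and in refed cells -0.61 and 0.93. No list was matched on length for these ratios. Differences of genes and lists between fractions, within starved or refed cells, may therefore partly follow length. Longer mRNAs may carry more ribosomes, but a lowest rho of 0.533 is the pattern itself and does not test that, so it stays open. Brightness might have produced the relation, but within 5 bins of brightness rho ranged from 0.5 to 0.748, which excludes that. The difference between fractions ran the other way, from 0.209 for the shortest to -0.251 for the longest genes, so part of any shift of a list of short genes on refeeding goes with length.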
